A study of Arabidopsis thaliana with 6 samples.

How the data were processed

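The series holds 6 Affymetrix arrays of biotin-labelled total RNA from whole above-ground Arabidopsis rosettes, 1 array per condition. The deposited values are intensity signals on a linear scale, computed with MAS5, per the submitters' processing notes. The MAS5 version, its settings and the detection calls are not given in the sources used here. The mean of the values between the 2nd and 98th percentile was between 99.7 and 99.9 on all 6 arrays, so the deposited intensities had been brought to a common level and were not rescaled; a rescaling would have been made at a difference of over 10%. There were 0 missing values and 121 values of 0.

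Values under the floor, the 40th percentile of all values pooled (26.2), were set to it, and log2 was taken. Such a floor keeps ratios of dim probe sets small and makes the fold of a gene under it a lower bound. Of the 22810 probe sets, 64 are controls, 13513 are paired with 1 gene in the platform annotation, 503 with several and 8730 are not listed there and stay unnamed here. Each gene was represented by its probe set with the highest mean log2 value, which mattered for 146 genes with several. Of the 13356 genes, 13286 matched the RefSeq table of assembly TAIR10.1, which was used for symbols and locus names; no build is named for the deposited values, so no coordinates are printed. The annotation leaves out many well-known genes: 50 of the 398 loci in the gene lists drawn up before the data were examined are paired with a probe set, and of 14 genes that were to be named in any case (among them CHS, HY5, PR1 and PAL1) only PDF1.2 is. The others were not analysed here. Probe sets not paired with 1 gene had a median signal of 55.5, against 32.4 for those paired, so the genes described are the dimmer part of the array.

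A gene was counted as higher or lower at a difference of at least 2-fold. No test was possible with 1 array per condition, and no p-value is given. Genes are named by a rule fixed before the data were examined: the 8 highest and 8 lowest ratios of the UV-B against UV-A comparison (also at least 2-fold in the same direction against visible light) and of each inoculated array against mock, the 5 highest and 5 lowest of UV-A against visible light and of rpp7 against inoculated Col-5, all above the floor on both arrays; the 8 genes with the largest smallest ratio over UV-B and both inoculations; the 3 members of each list farthest in the direction of its median where the list stood apart; and the 3 largest bounds each way. Other members of the gene lists are named as examples and were chosen with their values in view, as were the genes named for the visible light against mock comparison and the 12 genes drawn in the figure of signals.

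Of 24 gene lists and cell type marker lists fixed beforehand, 8 had the minimum of 3 measured members. Because of this, 23 supplementary lists were built from locus and symbol families in the annotation before any gene's signal was looked at. A list's median was placed among the medians of 10000 random lists of the same size matched on mean level in 20 bins, as a description of these arrays, and a list was said to stand apart at or below percentile 2.5 or at or above percentile 97.5. A median on the matching side of 0 was also required, which the fixed rule did not state. Percentiles under the alternatives used 2000 random lists. Over 31 lists and 6 comparisons, 40 of 186 medians stood apart, where 9.3 would for lists of independent genes.

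Shared genes were counted among genes above the floor on at least 1 array of each comparison, and set beside the product of both counts divided by the number of those genes. UV-B was taken against UV-A there so that no array entered both ratios. Where 2 comparisons shared a control array, 100 sets of unchanged arrays were simulated with noise that depended on level, taken from the pair of inoculated Col-5 and mock arrays, which overstates the noise where those conditions differ. Alternatives planned before the data were examined were quantile normalization, a floor at the 25th or the 60th percentile, a pseudocount (the 25th percentile, 12.1) without a floor, a 3-fold threshold, probe sets with cross-hybridisation suffixes left out, the mean over a gene's probe sets, and visible light in place of UV-A in the overlaps. Counts over all probe sets, counts and overlaps without plastid-encoded genes and the comparison of rpp7 with both Col-5 arrays were added after the data were seen.

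The computation was tested on simulated data for UV-B against UV-A with 13356 genes. All 50 genes raised 4-fold were called, 78.0% of those lowered 4-fold, and all 23 that were lowered 4-fold from over 4 times the floor. The share of 78.0% missed the criterion first set, over 80%, because the floor hides part of a lower signal, and the criterion was then limited to those 23 genes. Of unchanged genes, 0.69% were called. All 40 simulated lists of 15 genes with a shift of 0.5 on the log2 scale stood apart, and 3 of 40 without a shift did. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.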

Results

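Transcript levels in *Arabidopsis thaliana* rosettes were measured on 6 Affymetrix arrays, each carrying 22810 probe sets, with 1 array for each of 6 conditions. For 3 arrays, Col-0 plants stood under 20 µmol m-2 s-1 of visible light for 1.5 photoperiods. The first of these received 4.5 µmol m-2 s-1 of UV-B from fluorescent tubes behind cellulose diacetate, a film that passes UV-B. The second received 3.7 µmol m-2 s-1 of UV-A from the same kind of tube behind a polyester film that holds UV-B back, and the third had visible light alone. The other 3 arrays concern *Peronospora parasitica*, the oomycete of downy mildew. Its Hiks-1 isolate was sprayed on Col-5 plants, which resist it, and on rpp7 plants, a susceptible mutant made from Col-5, while mock Col-5 plants were sprayed with water. These plants stayed under lids at 18 °C for 3 days. Whole rosettes were taken 6 hours into the light period in both experiments. The series title sets the response to UV-B beside the response to biotic stress, which is the question the overlap comparisons address. There were no replicates, so no difference below has a test, and the number of arrays limits the precision. Values are array signals in intensity units, set to no less than a floor of 26.2, and 13356 genes were measured. Where the dimmer array lay under the floor, a fold is written as "at least".

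UV-B against UV-A was the comparison nearest to UV-B alone. Genes of flavonoid glycosylation and of the UV-B light response were higher under UV-B. HYH (AT3G17609), a bZIP factor related to HY5, had a signal of 196.9 under UV-B and lay under the floor under UV-A and in visible light, a difference of at least 7.52-fold. UGT78D2 (AT5G17050), a flavonoid glucosyltransferase, had 242.0 against 59.9 under UV-A, and AT1G06000, a flavonol rhamnosyltransferase, had 312.3 against 39.2. UGT84A1 (AT4G15480), which glucosylates hydroxycinnamic acids, was at least 2.39-fold higher, while UGT78D1 (AT1G30530) had 52.7 and 53.7. The list of UV-B photomorphogenic and flavonoid genes had 4 measured members of 23, with 3 at least 2-fold higher and a median log2 ratio of 1.63, at percentile 99.98 among 10000 random lists matched on level. The anthocyanin list, with 3 of 8 members measured, did not stand apart: its median was 0.10 at percentile 96.8, with UF3GT at a bound of 1.98-fold.

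Genes of the salicylic acid and pathogen response lists were higher under UV-B as well. The genes with the largest ratios and bounds, given first, were ranked among all genes and are not members of these lists. AT2G41730 had the largest ratio of all genes above the floor on both arrays, with 1166 under UV-B, 29.9 under UV-A and 26.4 in visible light, or 39.0-fold against UV-A. AT3G48640 followed at 12.0-fold, AT1G05340 at 11.2-fold, the MATE-family transporter gene AT2G04070 at 9.69-fold, the beta-glucanase gene AT4G16260 at 8.72-fold, the calmodulin-like gene AT3G01830 at 8.46-fold and AT4G01870 at 8.26-fold. Against an UV-A signal under the floor, another MATE-family gene, AT2G04050, was at least 11.9-fold higher, AT5G62210 at least 11.5-fold and the dehydrogenase-like gene AT1G09500 at least 9.11-fold. Of the salicylic acid list, 3 of 30 members were measured and all were higher: GRX480 (AT1G28480), a glutaredoxin, by 4.62-fold, the transcription factor WRKY53 (AT4G23810) by 2.00-fold and SAG101 (AT5G14930), a lipase-like immune regulator, by 1.57-fold. That list's median of 1.00 lay at percentile 98.1. In the list of glutathione transferase and oxidative stress genes 3 of 34 members were measured. AT2G21640 was 7.21-fold higher and the zinc finger factor STZ (AT1G27730) 6.85-fold, and the median of 2.78 lay at percentile 99.99. Neither encodes a glutathione transferase, and the third member, GSTU25, was under the floor on every array. A supplementary list of 11 tau glutathione transferase genes had 5 members above the floor, 1 higher and 4 lower, GSTU18 with 152.9 against 354.2. With so few above the floor its median could only be 0, so it could not stand apart. A supplementary list of 20 pathogen and salicylate responsive genes, drawn up from the annotation before gene signals were looked at, had a median of 0.84, above all 10000 random lists. Among its members 9 were at least 2-fold higher and 0 lower, led by AT3G18250 (897.7 against 205.3), AT1G57630, which encodes a TIR-domain protein (379.2 against 95.1), and AT5G18470 (385.7 against 108.1). The defensin genes PDF1.2 (AT5G44420) and PDF1.2b (AT2G26020), markers of jasmonate and ethylene signalling, were 5.42-fold and 5.69-fold higher. PDF1.2b was read, here and below, from a probe set with a cross-hybridisation suffix, so its signal may not be independent of PDF1.2. AT2G04400, which encodes indole-glycerol-phosphate synthase of tryptophan synthesis, was 2.65-fold higher, and WRKY6 at least 3.52-fold. The receptor gene EFR (AT5G20480) was at least 2.34-fold higher and the kinase gene BIK1 (AT2G39660) 1.92-fold.

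Histone, cold and plastid-encoded genes were lower under UV-B, and so were single genes of growth. The expansin gene EXPA8 (AT2G40610) had 178.6 under UV-B, 1127 under UV-A and 1013 in visible light. IAA29 (AT4G32280), of the auxin response, lay under the floor under UV-B and had 94.3 under UV-A and 207.3 in visible light. PRL (AT4G02060), the MCM7 subunit of the replication helicase, was 2.04-fold lower. All 4 histone genes of a supplementary list were lower, with 3 of them at least 2-fold lower, namely HTB2 (2.73-fold), HTB11 (2.23-fold) and HTB1 (2.09-fold), and the list median was -1.11 at percentile 0.29. COR15A (AT2G42540) had 166.5 against 776.7 and the dehydrin gene COR47 (AT1G20440) 386.1 against 1017, while LTI30 had 220.0 and 229.6. Those 3 measured members of 14 gave the abscisic acid, cold and dehydration list a median of -1.40, at percentile 0.49. The 8 lowest genes above the floor on both arrays were AT1G04040 (7.86-fold lower), AT3G26450, the plastid-encoded psaA (6.94-fold), AT5G12050, EXPA8 (6.31-fold), AT4G30650, AT1G30250 and the thionin gene AT1G66100 (5.61-fold). AT3G56060, AT5G50740 and AT1G68600 lay under the floor under UV-B and were at least 5.37-fold, 4.77-fold and 4.32-fold lower. Plastid-encoded photosynthesis genes had a median of -0.65, below all 10000 random lists, with 12 of 45 members at least 2-fold lower, psbH by 4.65-fold and ndhA by 3.29-fold among them. Their median signal was 291.6 under UV-B, 303.0 on the mock and 297.6 on the inoculated rpp7 array, the latter arrays without UV-B. The 25S ribosomal RNA signal was lower than under UV-A too, at 498.1 against 1119, but higher than in visible light, at 89.7. Against visible light ndhI was 3.93-fold lower. Plastid ribosomal protein genes had a median of -0.57 over 15 members, with rpl36 2.18-fold, rpl22 2.05-fold and rps3 1.84-fold lower than under UV-A, and against visible light rps19 had 396.3 against 992.9 and rps14 33.1 against 73.1. Nuclear photosynthesis genes of the list drawn up beforehand had a median of -0.37, and at percentile 7.53 they did not stand apart: LHCB4.2 had 2105 against 3099 and PSAN 1506 against 2344. Genes of cytosolic ribosomal proteins were slightly higher, with 95 of 108 members higher by any amount and 2 at least 2-fold (AT4G39200 by 3.90-fold and AT2G20450 by 2.11-fold). AT3G16780 was 1.88-fold higher, AT4G10450 had 516.4 under UV-B against 238.9 in visible light, and the list median of 0.27 lay above all 10000 random lists.

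In total 460 genes were at least 2-fold higher and 509 at least 2-fold lower under UV-B than under UV-A. Against visible light the numbers were 633 and 700, and 412 genes were higher and 413 lower against both comparators. The larger number of lower genes was not kept at a 3-fold threshold, with 154 higher and 95 lower against UV-A, 245 and 180 against visible light and 141 and 81 against both. It was also turned by quantile normalization, with 474 higher and 439 lower against UV-A, and with the floor at the 60th percentile, with 286 and 269. The UV-B against visible light medians had the same sign for each list named above as standing apart, at 1.81 for the UV-B list, 2.12 for the 20 pathogen responsive genes and -0.63 for the plastid-encoded genes. In simulated arrays of UV-B against UV-A, 44.0% of genes lowered 2.5-fold were called and 82.0% of those raised 2.5-fold, because the floor hides part of a lower signal.

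**Figure D1:**
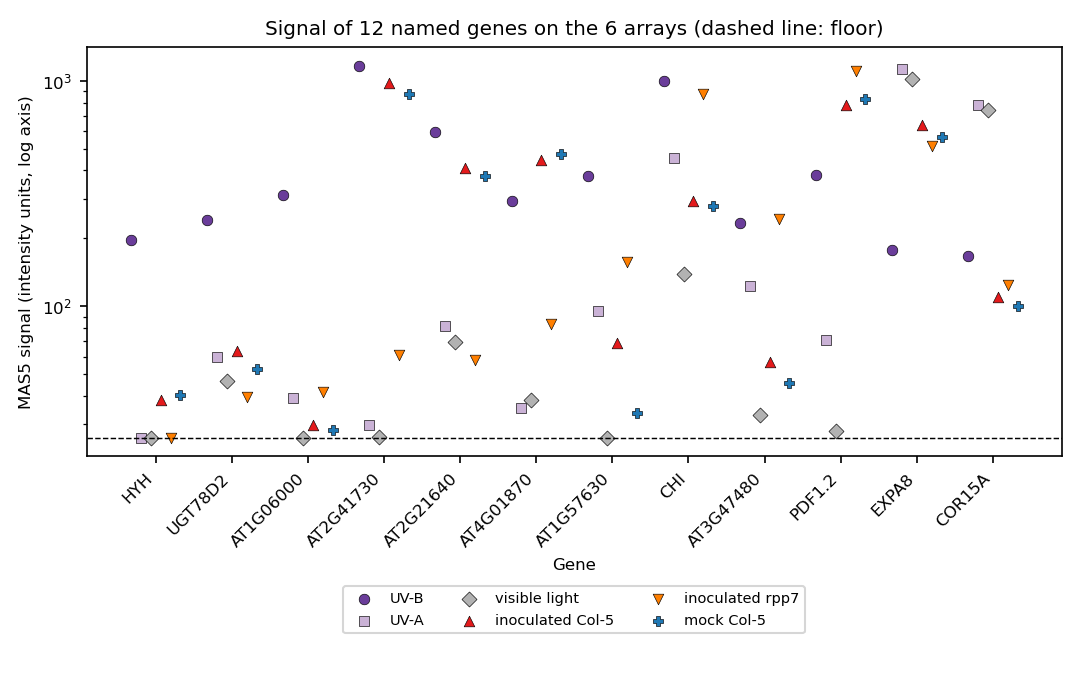
Array signal (intensity units, logarithmic axis) of 12 named genes on the 6 arrays, with 1 point per array, values under the floor drawn at the dashed line of 26.2, and no error bars because there were no replicates. AT2G41730 reached 1166 under UV-B and 870.6 on the mock array but 29.9 under UV-A and 60.8 on the inoculated rpp7 array, whereas HYH reached 196.9 under UV-B and at most 40.4 elsewhere. The AT2G41730 probe set has a cross-hybridisation suffix.

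UV-A against visible light showed few genes at least 2-fold apart, and several of these respond to pathogens. PDF1.2b was 3.90-fold higher under UV-A, AT3G47480, which encodes a calcium-binding protein, 3.72-fold, AT1G13470 3.36-fold, the chitinase gene named CHI in the reference (AT2G43570) 3.28-fold and AT2G18690 3.09-fold. AT1G57630, AT1G19020 and AT4G32605 lay under the floor in visible light and were at least 3.63-fold, 2.73-fold and 2.97-fold higher. Of the 20 pathogen and salicylate responsive genes 8 were at least 2-fold higher and 0 lower, and the median of 0.70 lay above all 10000 random lists. Their signals were thus ordered visible light, UV-A, UV-B, with medians of 58.3, 106.5 and 279.0. The lowest genes were ndhG (3.35-fold), AT5G60840 (2.56-fold), AT5G22460 (27.0 against 67.5), CLUB (2.37-fold) and AT3G18800 (2.24-fold), and ndhF, AT2G15520 and AT5G47380 were lower by at least 3.36-fold, 2.22-fold and 2.04-fold. HYH and UGT84A1 were under the floor on both arrays, and UGT78D2 had 59.9 and 46.8. In all, 53 genes were higher and 20 lower. These were 0.55% of genes, below the 0.69% of unchanged genes called in simulated arrays whose noise was taken from this same pair. That noise includes any difference between these lights, so the simulation cannot separate the 2. The count alone does not set single genes apart from noise. With the floor at the 25th percentile the numbers were 128 and 137, so the excess of higher genes was not kept.

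In Col-5 plants inoculated with the isolate they resist, plastid-encoded genes led the difference from mock plants: rpl16 had 298.9 against 67.3 on the mock array, atpF 418.5 against 96.1, psaA 1255 against 333.9, accD 203.2 against 55.8, atpH 280.6 against 79.9, ndhJ 521.7 against 150.4, psaC 260.5 against 77.8 and psbB 146.3 against 46.9. The median of 45 plastid-encoded photosynthesis genes was 0.76, above all 10000 random lists, with 17 members at least 2-fold higher and 0 lower. Plastid ribosomal protein genes had a median of 0.70, with rps15 2.61-fold higher beside rpl16 and rpl14. The 10 nuclear photosynthesis genes fixed beforehand had a median of -0.05 at percentile 45.6. Across the 6 arrays the median signal of the plastid-encoded photosynthesis genes was 644.2 on the inoculated Col-5 array, 657.9 under UV-A and 574.0 in visible light, and 303.0 on the mock, 297.6 on the inoculated rpp7 and 291.6 on the UV-B array.

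Pathogen and salicylate responsive genes of the list of 20 differed less than 2-fold between inoculated Col-5 and mock, with 1 exception. AT2G17740 was 1.79-fold higher, AT3G28510 at least 1.78-fold, and outside that list STZ was 1.85-fold and WRKY53 1.51-fold higher. PDF1.2 had 781.4 against 832.6, CHI 294.4 against 278.7 and AT3G18250 324.4 against 287.8. Of the 20 pathogen and salicylate responsive genes 1 was at least 2-fold higher, AT1G57630 by 2.05-fold, and the median of 0.13 lay at percentile 99.5, though it was 0 with the floor at the 60th percentile. Among genes under the floor on the mock array, the largest bounds were those of rpl14 (2.92-fold), AT4G37290 (2.35-fold) and AT2G07751 (2.18-fold). Genes lower in inoculated Col-5 were AT1G63530 (2.88-fold), ARLA1C (2.19-fold), EXLA1 (2.15-fold), AT1G75200 (2.14-fold), the glutaredoxin-family genes AT4G15690 and AT4G15680 (2.14-fold and 2.06-fold), AT1G62510 (2.03-fold) and AT2G41250 (2.01-fold). Bounds for lower genes reached 1.93-fold for AT5G05670, 1.90-fold for AT5G47420 and 1.81-fold for AT5G47050. In all, 39 genes were at least 2-fold higher and 9 lower, and 22 of the 39 were plastid-encoded, which left 17 higher and 9 lower without them. These were 0.36% of genes, below the 0.69% of unchanged genes called in simulated arrays with noise from the UV-A and visible light pair. That pair had a larger SD of log2 ratios, 0.34 against 0.28, so a lower share was to be expected and decides nothing. With no replicates, the count alone does not set single genes apart from noise, though all 22 plastid-encoded genes among those counted were higher. The total of 48 depended on the treatment of dim genes, at 203 with the floor at the 25th percentile, 83 with a pseudocount and 22 with the floor at the 60th percentile. This pair of arrays also had the smallest spread of all 15 pairs, with an SD of log2 ratios of 0.28 over 6917 genes above the floor on both.

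Inoculated rpp7 plants, in which the isolate can grow, had higher levels of pathogen responsive transcripts than mock plants. AT5G55450, a lipid-transfer family gene, had 1058 against 194.5, CHI 872.9 against 278.7, AT3G47480 244.8 against 46.0, AT3G18250 962.2 against 287.8, AT5G18470 300.4 against 97.6 and AT1G57630 157.9 against 33.6. Of the 20 pathogen and salicylate responsive genes 10 were at least 2-fold higher and 1 lower, AT1G21520 by 3.46-fold, and their median of 0.92 lay above all 10000 random lists. The salicylic acid list had a median of 0.64 at percentile 94.7 and did not stand apart, with WRKY53 2.41-fold higher and GRX480 1.76-fold lower. PDF1.2 and PDF1.2b had 1109 against 832.6 and 1149 against 1138. The 8 highest genes were ARPN (AT2G02850), a plantacyanin gene, at 5.91-fold, AT5G55450, AT5G03120 at 5.43-fold, AT3G47480, AT3G60540 at 4.95-fold, AT1G57630, the aspartyl protease gene AT3G54400 at 4.43-fold and AT1G62500 at 4.24-fold. AT2G44240, AT3G51330 and ATPMEPCRB (AT4G02330), a pectin methylesterase gene, lay under the floor on the mock array and were at least 9.74-fold, 6.38-fold and 5.69-fold higher. Cytosolic ribosomal protein genes had a median of 0.23, above all 10000 random lists, led by AT4G30800 (2.07-fold), AT3G47370 (1.83-fold) and AT3G16780 (1.74-fold), with 75 of 108 members higher by any amount and 31 lower, AT5G39850 by a log2 ratio of -1.08. The 3 cold and dehydration genes had a median of 0.83 at percentile 99.2, with LTI30 2.17-fold, COR47 1.78-fold and COR15A 1.25-fold higher.

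The lower genes in inoculated rpp7 included some that were higher under UV-B, among them AT2G41730 and AT2G21640. AT3G45730 had 33.5 on the inoculated rpp7 array against 721.1 on the mock array, AT5G40690 29.7 against 505.6, AT2G41730 60.8 against 870.6, AT5G14730 36.5 against 382.5, the nitrate transporter family gene AT3G21670 71.3 against 535.8, AT4G33980 35.9 against 247.2, AT2G21640 58.1 against 379.8 and AT5G61820 168.2 against 1051. AT2G04050, UGT73B1 (AT4G34138) and AT2G18190 were at least 19.6-fold, 11.9-fold and 9.39-fold lower. The oxidative stress list had a median of -0.97 at percentile 0.46, with 2 of its 3 members above the floor and STZ 1.96-fold lower. Glucosinolate genes had a median of -0.85 at percentile 2.45, with AT2G31790 2.33-fold and BCAT4 1.81-fold lower and UGT74B1 1.12-fold higher, and this list no longer stood apart with the floor at the 25th or 60th percentile or with cross-hybridising probe sets left out. In all, 277 genes were at least 2-fold higher and 284 lower, and 424 and 368 with the floor at the 25th percentile. Against both the mock and the inoculated Col-5 array, a comparison added after the data were seen, 171 were higher and 203 lower. A mock-sprayed rpp7 array was not analysed here, so genotype and infection are not separated. By SD of log2 ratios the inoculated rpp7 array lay nearer UV-A (0.45) and visible light (0.49) than inoculated Col-5 (0.54) or mock (0.56).

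Against inoculated Col-5 directly, inoculated rpp7 had 235 genes at least 2-fold higher and 281 lower. The highest were EXLA1 (AT3G45970), an expansin-like gene, with 226.6 against 33.6, AT5G55450 (5.99-fold), AT5G03120 (5.59-fold), PRA1.B4 (4.87-fold) and ARPN (4.85-fold), and AT2G44240, AT3G51330 and AT5G46230 reached bounds of 9.74-fold, 6.38-fold and 5.95-fold. The lowest were AT3G45730 (20.7-fold), AT2G41730 (16.0-fold), AT5G40690 (14.4-fold), AT5G14730 (10.1-fold) and AT2G21640 (7.09-fold). AT2G04050, AT2G18190 and UGT73B1 were at least 23.4-fold, 11.2-fold and 10.2-fold lower. Of the 281 lower genes 22 were plastid-encoded.

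The overlap of UV-B with inoculation ran both ways, and for rpp7 the genes at least 2-fold apart in opposite directions outnumbered the shared ones. The mock comparator bears on this, as genes higher under UV-B than under UV-A were also higher in mock than in visible light (Pearson r 0.55). AT2G21640, an opposite gene, had 379.8 on the mock, 412.0 on the inoculated Col-5, 58.1 on the inoculated rpp7 and 69.3 on the visible light array. Opposite directions thus need not mean that infection lowers such genes. AT1G57630 was the single gene at least 2-fold higher under UV-B against UV-A and in both inoculated conditions against mock, with a smallest log2 ratio of 1.04. The next genes by smallest ratio were AT1G14060 (0.86), AT4G23610 (at least 0.84), AT1G51920 (0.82), AT4G12500 (0.73), AT1G26380 (0.73), AT5G13200 (0.72) and AT3G28510 (at least 0.67). UV-B and inoculated rpp7 shared 36 higher genes, where 16.2 are given by independent lists of these sizes, and 23 lower genes against 18.9. Genes higher under UV-B and lower in inoculated rpp7 numbered 61, with 16.3 given by independent lists, and genes lower under UV-B and higher in inoculated rpp7 numbered 58, with 18.8. Across 7321 genes the log2 ratios correlated at a Pearson r of -0.18 and a Spearman rho of -0.14, where genes are not independent replicates. With rpp7 set against inoculated Col-5 in place of mock, 64 and 57 genes stood in opposite directions and 24 and 28 were shared. Both plants were inoculated there, so these counts do not separate inoculation from the rpp7 genotype or the outcome of infection. For UV-B and inoculated Col-5 the shared genes were 6 higher, against 2.31 for independent lists, and 2 lower, against 0.62, while 3 were higher under UV-B and lower in inoculated Col-5, against 0.53, and 11 lower under UV-B and higher in inoculated Col-5, against 2.67. With plastid-encoded genes left out, an alternative added after the data were seen, 1 of these 11 remained, so 4 genes stood in opposite directions and 8 in the same. The r was -0.04 and the rho -0.05 over 7306 genes. For shared higher genes the ratio to independent lists was 2.60 for Col-5 and 2.22 for rpp7, and with visible light in place of UV-A 1.58 and 2.45, so neither inoculation had the larger ratio in both. With visible light in place of UV-A, UV-B and rpp7 shared 55 higher genes, against 22.5 for independent lists, and 20 lower genes, against 25.7, so the excess of shared lower genes was not kept. Genes in opposite directions then numbered 86 and 78. None of these comparisons shares an array between its 2 ratios.

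**Figure D2:**
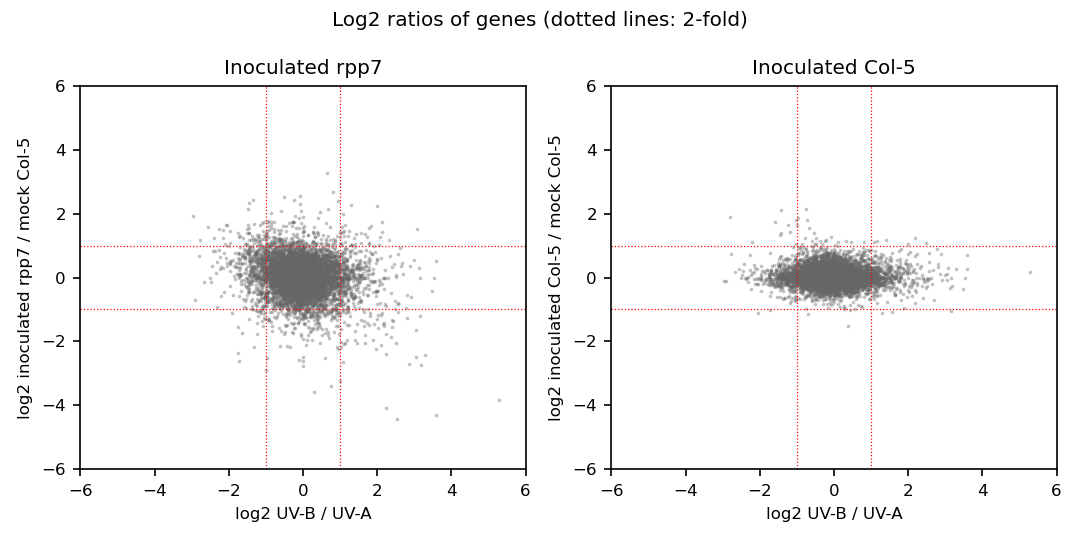
Log2 ratio of UV-B over UV-A (horizontal axes) against the log2 ratio of inoculated rpp7 (left) and inoculated Col-5 (right) over mock, with 1 point per gene for 13356 genes and dotted lines at 2-fold. At least 2-fold differences in opposite directions (61 and 58 genes on the left) outnumbered those in the same direction (36 and 23). Genotype and infection are not separated on the left. Genes higher under UV-B than under UV-A were also higher in mock than in visible light (Pearson r 0.55), which bears on both panels.

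Inoculated Col-5 and inoculated rpp7 shared 5 higher genes, against 1.29 for independent lists, and 5 lower genes, against 0.35, when both were set against the mock array. In simulated unchanged arrays with a shared control, 0.09 higher and 0.44 lower genes were shared on average. The ratios had a Pearson r of 0.28, a Spearman rho of 0.31 and a covariance of 0.046, and the simulated arrays gave an r of 0.50 and a covariance of 0.038. The covariances differed by 0.0078. UV-B and UV-A, both against visible light, had an r of 0.56, where simulated unchanged arrays gave 0.50, and a covariance of 0.144 against a simulated 0.036. They shared 43 higher genes, against 3.78 for independent lists and 0.08 in the simulated arrays, and 13 lower genes, against 1.78 and 0.34. The simulated noise, from the inoculated Col-5 and mock pair (SD 0.28), may be too low here, as UV-A and visible light had an SD of 0.34. Equal noise with a shared control gives an r near 0.50 by itself.

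The comparators of the experiments, visible light and mock, differed in defensin, cold and plastid genes. PDF1.2 had 28.1 in visible light and 832.6 on the mock array, PDF1.2b 42.0 and 1138, AT2G41730 26.4 and 870.6, AT3G45730 31.9 and 721.1, AT4G01870 38.7 and 472.4 and AT2G21640 69.3 and 379.8. COR15A was 7.41-fold higher in visible light, COR47 had 1406 and 551.7, and LTI30 had 244.3 and 93.0, a list median of 1.39 at percentile 99.9. The 20 pathogen responsive genes had a median of -0.48, below all 10000 random lists, with 6 members at least 2-fold lower in visible light, CML41 by 2.76-fold among them, though this list no longer stood apart with the floor at the 60th percentile. The oxidative stress list had a median of -2.28 at percentile 0.010 and the glucosinolate list -1.06 at percentile 0.63. Plastid-encoded photosynthesis genes were higher in visible light, with a median of 0.84 and 19 of 45 members at least 2-fold higher, ndhE by 6.96-fold and ycf3 by at least 5.97-fold among them. Plastid ribosomal protein genes had a median of 0.70 there, with rpl20 2.48-fold higher. Of 11 nuclear photosynthesis genes of a supplementary list 7 were lower and 4 higher, with a median of -0.34 at percentile 1.11, whereas the 10 of the list fixed beforehand had a median of 0.32 at percentile 94.3, with 7 higher and 3 lower. In the supplementary list the lowest were NdhN at 374.8 against 676.5, NdhL at 496.6 against 833.2 and PGRL1B at 166.1 against 265.1. CYP71B cytochrome P450 genes had a median of -0.13, below all 10000 random lists, with CYP71B23 at 85.1 against 215.1 and CYP71B22 at 62.1 against 134.7, but a median of 0 with the floor at the 60th percentile. In all, 266 genes were at least 2-fold higher in visible light and 303 lower. The numbers were 547 and 406 with the floor at the 25th percentile, 115 and 203 with the floor at the 60th, and 39 and 101 at 3-fold, so the direction of the split depended on the setting. Accession, light, temperature and spraying all differed between these arrays.

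**Figure D3:**
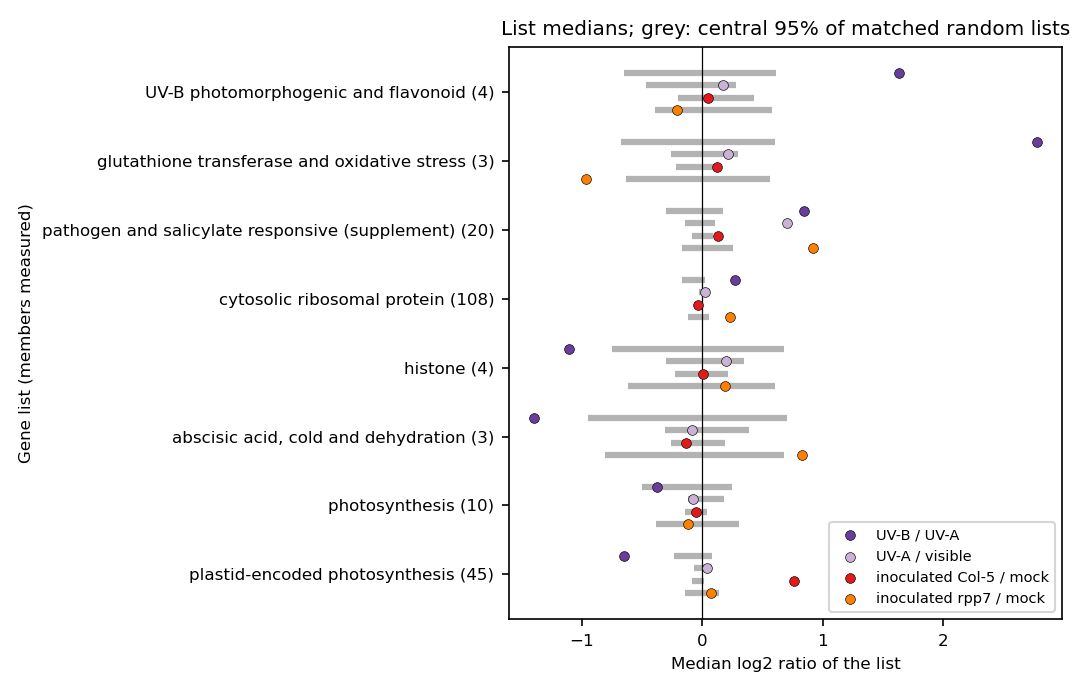
Median log2 ratio of 8 gene lists (number of measured members in brackets) in 4 comparisons, with grey bars for the central 95% of 10000 random lists of the same size matched on mean level, which describe these arrays and are not replicate errors. Pathogen and salicylate responsive genes were higher under UV-B (0.84), under UV-A (0.70) and in inoculated rpp7 (0.92). The oxidative stress list, with 3 of 34 members measured, had medians of 2.78 under UV-B and -0.97 in inoculated rpp7. Both are the values of STZ, as GSTU25 was under the floor on every array.

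Signs of RNA quality differed between arrays. Cell type makeup could not be judged, with 1 measured marker gene each for trichomes, guard cells and roots and 0 for floral organs and for xylem and phloem. The probe set for 25S ribosomal RNA went from 57.1 (inoculated rpp7) to 1119 (UV-A). The ratio of 3' to 5' signal was between 3.26 (inoculated rpp7) and 6.22 (UV-B) for actin, between 1.33 and 2.04 for GAPDH and between 1.72 and 2.40 for ubiquitin. The trichome gene TRY was at 28.9 or less on every array, and the guard cell gene FMA went from under the floor (UV-B) to 55.3 (inoculated Col-5). PYK10, a gene of roots, was between 113.3 (UV-B) and 207.7 (inoculated Col-5). Of the reference genes, PEX4 was between 220.7 and 312.9, AT2G28390 between 83.1 and 117.6, and AT4G34270 between 86.8 and 132.5. Among the pairs of arrays, SDs of log2 ratios over genes above the floor on both went from 0.28 (inoculated Col-5 and mock) and 0.34 (UV-A and visible light) to 0.76 (UV-B and visible light).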

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

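Every test described here was chosen after the results it concerns were seen.

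Between the inoculations of Col-5 and rpp7, both against mock, 2 genes differed at least 2-fold in opposite directions, EXLA1 with log2 ratios of -1.11 and 1.65 and PRA1.B4 with signals of 28.3 in Col-5 and 137.7 in rpp7 against 56.6 in mock, and the difference was not tested. Between UV-B and UV-A, both against visible light, 1 gene did, the plastid-encoded psaA with -1.56 and 1.24, also not tested. The control probe set for 25S ribosomal RNA, which no comparison used, had a signal of 1119 on the UV-A and 498.1 on the UV-B array against 89.7 in visible light. Among 9233 probe sets paired with no gene or with several, 956 differed at least 2-fold between UV-B and UV-A, or 10.4% of them against 7.26% of the genes, while in UV-A against visible light 50 were higher and 20 lower. Their median signal was higher, 55.5 against 32.4 for probe sets paired with 1 gene, so fewer may be hidden by the floor.

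Plastid-encoded genes were higher in inoculated Col-5 than in mock, and their levels put UV-A, visible light and inoculated Col-5 together at 574.0 or more and the other arrays at 303.0 or less, across both experiments. A higher level of all photosynthesis transcripts is argued against by 21 nuclear photosynthesis genes, whose median log2 ratio was -0.053 with a median absolute deviation of 0.085. Carry-over of RNA without a poly(A) tail may contribute, also to the lower plastid levels under UV-B than under UV-A, and it would raise 25S ribosomal RNA along with plastid RNA: in 6 of 9 pairs of an array with a high and an array with a low plastid median the 25S signal was higher on the first. That explanation and a response of the chloroplast to inoculation or to UV-B cannot be told apart, because that probe set follows the plastid genes only in part. Of 15 mitochondrion-encoded genes, which also lack stable tails, 5 to 8 were above the floor in each comparison. Their list median was thus held at or near 0, and not standing apart says nothing on carry-over. Of those above the floor 5 of 5 were higher in inoculated Col-5 than in mock and 7 of 7 higher in visible light than in mock. Under UV-B 4 of 6 were lower than under UV-A and 7 of 8 lower than in visible light. However, 6 of 7 were also lower under UV-A than in visible light, where the plastid-encoded photosynthesis median was 0.04.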

How the results depend on the processing

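No paired analysis was possible because each condition had 1 array, and for the same reason no array could be left out. Under the alternatives, 73 counts stayed within 1.5 times of their value and 52 did not. None of the 40 list medians that stood apart turned sign, and 223 of 240 recomputed medians still stood apart. No recomputed ratio of the genes ranked highest or lowest turned sign, though 62 of 404 moved by over 0.28 on the log2 scale. The 404 do not include AT2G41730 and PDF1.2b with cross-hybridising probe sets left out, so these genes were not checked under that setting. Each floor sets how many dim genes can be counted; whether the genes gained at the 25th percentile are noise or differences that a higher floor hides was not tested. Signal over background limits what can be seen, since 8514 of 13356 genes were above the floor on any array.

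With the floor at the 25th percentile, the counts of higher and lower genes together were 265 for UV-A against visible light, 203 for inoculated Col-5 and 953 for visible light against mock. Shared genes were then 14 higher and 6 lower for UV-B and inoculated Col-5, and 24 higher and 13 lower for both inoculations. At the 60th percentile they were 761 for UV-B against visible light, 555 against UV-A and 484 against both, 34 for UV-A, 22 for inoculated Col-5, 339 for rpp7 against inoculated Col-5 and 318 for visible light against mock. Shared genes were 1 higher and 1 lower for UV-B and inoculated Col-5, 21 and 14 for UV-B and rpp7, and 3 and 2 for both inoculations. With a pseudocount and no floor, 160 genes were counted for UV-A against visible light (80 higher and 80 lower) and 83 for inoculated Col-5, UV-B shared 3 higher and 1 lower gene with inoculated Col-5 and 23 higher with rpp7, and 61 list medians stood apart. At 3-fold the counts were 425 for UV-B against visible light, 249 against UV-A and 222 against both, 8 for UV-A, 9 for inoculated Col-5, 131 for rpp7 against mock, 121 against inoculated Col-5 and 140 for visible light against mock. At that threshold UV-B and rpp7 shared 3 higher and 3 lower genes, and 0 were shared in either direction by UV-B and inoculated Col-5 or by both inoculations. Quantile normalization left 1 shared lower gene for UV-B and inoculated Col-5 and 3 shared higher genes for both inoculations. With visible light in place of UV-A, UV-B and rpp7 shared 55 higher and 20 lower genes.

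Over all probe sets, added after the data were seen, the counts were 2675 for UV-B against visible light, 1928 against UV-A and 1690 against both, 143 for UV-A, 79 for inoculated Col-5, 1165 for rpp7 against mock, 1070 against inoculated Col-5 and 1156 for visible light against mock. In UV-B against visible light 14.5% of the added probe sets were counted, against 9.98% of the genes. The added probe sets had a higher median signal, 55.5 against 32.4, and a probe set under the floor on both arrays cannot be counted. How far this accounts for the difference was not tested. Without plastid-encoded genes, also added, 26 were left for inoculated Col-5.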

Other observations

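The tests of the patterns weighed here were all chosen after the results were seen.

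UDP-glycosyltransferase genes, a supplementary list of 47, did not stand apart in any comparison, and their median was 0 in each. Under UV-B 15 were higher and 16 lower than under UV-A by any amount. Of these, 8 were at least 2-fold higher than under UV-A and 1 was lower, UGT72E1 (71.0 against 213.3), while in inoculated rpp7 5 were at least 2-fold lower than in mock and 0 higher. UGT87A2 had 590.4 under UV-B and 205.9 under UV-A, and UGT84A3 174.8 and 54.9. In inoculated rpp7 UGT84A3 had 52.6 against 216.1 on the mock array and UGT74D1 63.3 against 193.2. Of 12 genes of small heat shock proteins and chaperones, 3 were at least 2-fold higher under UV-B than under UV-A, among them AT3G09440 (1270 against 379.1) and Hsp70-2 (346.0 against 117.5), and 1 was lower, AT1G54050 (34.9 against 73.9). Their median was 0 at percentile 54.8, so this list did not stand apart either. With 6 of 12 members above the floor, 5 higher and 1 lower by any amount, the median was held at or near 0 and says little.

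Genes of cell wall families were compared between UV-B and both comparators, and no family stood apart against both. A gene under the floor on both arrays has a ratio of 0, however, which holds the median of such lists at or near 0. Members above the floor were mostly lower against both comparators. In the expansin and xyloglucan endotransglucosylase list 7 of 26 members were at least 2-fold lower and 0 higher than in visible light, with a median of -0.20 at percentile 0.090. EXPB1 was at least 3.29-fold lower and XTH16 had 40.8 against 112.9, but with the floor at the 60th percentile the median was 0. Against UV-A the median was 0 at percentile 50.3, the only value it could take with 12 members above the floor. Of those 12, 11 were lower, 6 of them at least 2-fold, and 1 was higher. Among 15 class 9 glycosyl hydrolase genes 4 were at least 2-fold lower than in visible light, with GH9C2 lower by 5.92-fold, GH9B8 by at least 3.77-fold and GH9B7 at 135.3 against 473.2. Their median lay at percentile 0.21, but this list no longer stood apart after quantile normalization, where its median was 0. Against UV-A 5 members were above the floor, so the median could only be 0 and did not stand apart. All 5 were lower than under UV-A, 4 of them at least 2-fold. Trichome birefringence-like genes had a median of -0.15 against UV-A at percentile 0.13, with TBL45 3.28-fold, TBL39 at least 2.35-fold and TBL25 2.32-fold lower. This list did not stand apart with the floor at the 60th percentile or with a pseudocount. Against visible light the median was 0 at percentile 56.4, but 12 of 22 members were above the floor, 10 of them lower and 2 higher. Members at least 2-fold lower numbered 5 against visible light and 3 against UV-A. In inoculated rpp7 against mock, 3 of 19 CYP71B cytochrome P450 genes were at least 2-fold lower, CYP71B36 by 3.04-fold, CYP71B24 by 2.16-fold and CYP71B5 at 47.2 against 94.6, though with the floor at the 60th percentile the list median was 0. Of 7 autophagy 8 genes 6 were lower by any amount, ATG8E by 1.83-fold, ATG8B by 1.66-fold and ATG8H by 1.42-fold, at percentile 2.15, which was not kept with the floor at the 60th percentile or with a pseudocount. Among SWEET sugar transporter genes, which did not stand apart, SWEET1 had 334.9 under UV-B against 147.4 under UV-A, and SWEET16 had 34.6 against 94.7.

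Genes higher under UV-B than under UV-A were also higher in mock than in visible light: 125 of 427 were at least 2-fold higher in both, against 16.9 for independent lists, with a Pearson r of 0.55 across 7415 genes between ratios that share no array. An exchange of the UV-B and mock arrays is argued against by the UV-B list, whose 4 measured members were higher on the UV-B array by a median of 1.73 on the log2 scale. The r was 0.56 after quantile normalization. That does not test scaling by a factor per array, which shifts all log2 ratios alike and leaves r unchanged apart from the floor. RNA quality cannot be told apart from other causes: the mean log2 ratio of 3' to 5' signal was 1.34 under UV-B and 1.14 in mock, against 1.31 under UV-A and 1.59 in visible light, and for GAPDH and ubiquitin, though not actin, UV-B and mock both lay below the others. A response of Col-5 plants to spraying, lids or the 18 °C room may also have raised such genes on the mock array, which stays open and untested, as do accession and light level.

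The inoculated rpp7 array lay nearer the visible light and UV-A arrays than both Col-5 arrays did. It also lay nearer those light arrays than the other arrays of its own experiment. Genes at least 2-fold apart from rpp7 numbered 305 for UV-A and 355 for visible light, against 516 for inoculated Col-5 and 561 for mock. Among 38 genes at least 4-fold apart between both light arrays and both Col-5 arrays, 71.1% were nearer the light arrays on the rpp7 array, and after quantile normalization 69.2% of 39 were. The arrays had a common level beforehand and the genes were selected again after normalization, so the kept share does not decide on scaling. The share of 71.1% argues, though not clearly, against an array of the light experiment under the rpp7 label. The limit set for this was a share under 75%. Of the 38 genes 11 lay nearer Col-5 levels: PDF1.2b had 1149 on the rpp7 array, 1138 on the mock array and 42.0 in visible light, and COR15A 124.6 on the rpp7 array, 110.5 on the inoculated Col-5 array and 741.3 in visible light. The UV-B array, with 932.7 and 166.5 for these genes, is not set apart by them, but genes with a known direction under UV-B argue against its exchange with the rpp7 array, HYH with 196.9 on the UV-B array and under the floor on the rpp7 array and UGT78D2 with 242.0 and 39.5. The 27 genes nearer the light arrays, all higher in Col-5, may depend on the rpp7 genotype, on infection or on handling that differed between plants, which the design confounds and which were not tested.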
